A study of Mus musculus with 2 samples.

How the data were processed

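The 2 samples were Tek-positive mouse embryo cells, 1 with floxed Rictor alleles and a Tie2-driven Cre and 1 control. Total RNA was extracted with TRIzol and sequenced, per the labels' protocols. FastQC 0.10.1, TopHat2 2.0.9, HTSeq, DESeq and the mm9 build are named in the submitters' processing notes, which give no order or settings. The deposited table holds 2 columns of whole numbers per Ensembl gene identifier. None of its 37681 lines is a header. The 2 value columns could not be matched to the samples by name and were not used, so no normalization, fold change or test was computed and the depth per sample is not given.

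Only the identifiers in the first column were analysed. They were matched, without version numbers, to the genes of the GENCODE M21 annotation (GRCm38). The 42 gene lists, holding 815 different entries, were written before the data were examined. Entries were counted by name, so a gene listed under different names counted more than once. An entry counted as covered when its symbol, or an older symbol listed with it, belonged to a matched identifier. The rule fixed for named genes put Rictor first and included a fixed set of genes for a check of cell composition. Its other parts ranked genes by their values and were not applied. Genes named in the report are Rictor, examples from that fixed set, and the erythroid genes without a matched row.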

Results

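The series holds 2 RNA-seq samples of mouse embryo cells positive for Tek, the receptor tyrosine kinase also called Tie2, which marks endothelial cells and part of the early blood lineage. The cells came from the aorta-gonad-mesonephros (AGM) region, a site where hematopoietic stem cells arise, at embryonic day 10 per the series title. Both sample labels also give an in vitro culture of 10 days, and whether this stands for a time in culture or for the embryonic age was left open. For both samples the label for doxycycline treatment reads No. The strain label reads AGM, so it names no mouse strain. In 1 sample, floxed Rictor alleles were combined with a Tie2-driven Cre recombinase, and the other was the control. The first is called Rictor-deleted after this genotype, and the loss of Rictor was not checked here. The control's label does not give its Rictor or Cre genotype. Rictor encodes a defining subunit of mTOR complex 2, a kinase complex that phosphorylates AKT.

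The design implies a single comparison, between the Rictor-deleted and the control cells, with 1 library on each side and so no replicate error. That comparison was not made here. The deposited table gives 2 whole numbers for each of 37681 Ensembl gene identifiers, and it has no line that names its columns. Nothing in the sample labels assigns either column to a genotype, taking their order as a label would have been a guess, and assigning one from a gene's own level would have assumed the outcome. The direction of any difference could therefore not be given. Values that need no such assignment, such as a gene's mean over both columns, were not computed either. The 2 columns were not used at all, and no expression level, fold change or depth is given for any gene.

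What the identifiers alone show is which genes the table covers. Of the 37681 identifiers, 32642 (86.6%) were found in the GENCODE M21 annotation, and 5039 were not. Protein-coding genes made up 20194 of the matched identifiers, and processed pseudogenes 3810. Rictor itself has a row, under ENSMUSG00000050310. In the GRCm38 build of that annotation, which differs from the mm9 build named in the submitters' processing notes, this protein-coding gene lies on the plus strand of chromosome 15, from 6708379 to 6800401.

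Of 815 different entries in 42 lists fixed before the data were examined, 802 had a row matched by symbol. Every member had one in 35 of the 42 lists, also in those of skeletal and cardiac muscle and of germ cells and pluripotency. Full coverage was therefore not particular to the lists named next. All 9 listed components and regulators of mTOR complex 2 had one, as did all 24 FOXO factors (which AKT regulates) and FOXO targets. The same held for all 37 genes of hemogenic endothelium and stem cell emergence, among them Runx1, Gfi1 and Gata2, and for all 25 pan-endothelial genes, among them Tek, Kdr and Cdh5. Of the 28 erythroid genes, 25 had a matched row, and Hbb-b1, Hbb-b2 and Ahsp did not. Matching was by symbol, so a gene without a match may still have a row under another symbol or among the 5039 unmatched identifiers. A row says only that the gene was among the features counted, not that it was expressed.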

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

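The alternatives planned before the data were examined (scaling, minimum value, pseudocount, fold threshold and the matching of random lists on mean expression) all act on values of the 2 columns and were not run. The checks of identifier matching given here were chosen after seeing the data. Taking only the first symbol of each list entry gave 794 covered entries, and adding RefSeq synonyms gave 803, against 802 in the report. The gene name table and the GENCODE annotation matched the same number of identifiers, 32642. Whether they are separate sources was not checked, so the equal number does not test the matching.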
